A study of Macaca mulatta with 9 samples.

How the data were processed

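The series measured gene expression in rhesus monkey ear skin fibroblasts, ES cells of the line R366.4 and iPS cells of the line M2, with 3 arrays each, 9 in all. Per the labels, biotinylated cRNA was made from total RNA by the standard Affymetrix protocol, and the replicates are technical. The deposited value table holds 1 intensity per probe set and array, on a linear scale from 1 to 19574.1 as the authors processed it. Software, background correction, summarisation and scaling are not given in the sources used here. Array medians differ, so the deposited intensity values were not equalised on their medians or quantiles, and 16539 values (3.48%) are exactly 1. Intensities stand in for depth on arrays, and the number of arrays limits the precision.

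The authors' deposited tables of the 3 comparisons hold the median intensity of the 3 arrays of each cell type, checked against the value table, for probe sets chosen by a filter not given in the sources used here. In the table of iPS against ES cells the iPS medians were multiplied by 1.188, which makes the medians of both columns equal at 177.39. These tables are described, set beside the calls made here, and used in 1 alternative to choose probe sets.

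Of 52865 probe sets, 24969 carry 1 gene symbol, 361 several and 27535 none in the platform annotation. No gene was named from a probe set with several. Symbols were updated through a gene table of the assembly T2T-MMU8v2.0, and no coordinates are given because the build behind the array design is not given in the sources used here. The 99 control probe sets were left out. Probe sets above an intensity of 22.45, the 40th percentile of all values, on at least 3 of the 9 arrays were tested, which left 36978 (70.1%). They represent 12217 named genes, 4824 of them with several tested probe sets. A gene is represented by its probe set with the highest mean log2 value, and probe sets that share sequence with other transcripts by design, as for LIN28B, DCN, FN1, H19, KYNU, DKK3 and COX7A1, are possibly cross-hybridising.

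Values were taken as log2(intensity + 16) without further normalization. All 9 arrays entered 1 linear model with a term per cell type (limma 3.58.1 in R 4.3.3, lmFit and eBayes), and each of the 3 pairs of cell types was tested with Benjamini-Hochberg adjustment. A call needs an adjusted p under 0.05 and a log2 difference of at least 1. limma calls were checked on simulated data with 100 probe sets changed by 3 log2 units among 36978, of which 80% to 91% were recovered over the 3 comparisons, and of 100 changed by 1.5 units 55% to 68%, with 6 to 19 false calls, the 19 for iPS against ES cells with shuffled observed residuals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

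Before the data were examined, 30 gene lists of 643 symbols were fixed, of which 455 have a probe set and 417 were tested. They cover reprogramming factors, pluripotency, fibroblasts and extracellular matrix, mesenchymal regulators, epithelial junctions, mitotic cell cycle, p53 and growth arrest, DNA methylation and chromatin, ectoderm, mesoderm, endoderm, trophoblast, germline, HOX genes, imprinted genes, interferon, inflammatory cytokines, glycolysis, mitochondrial respiration, lysosome, FGF, Nodal and WNT signalling, keratinocytes, melanocytes, endothelium, blood, muscle, immediate early genes, housekeeping and lists linked to the sex chromosomes, of which 0 genes were tested. Lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, over 84 tests together. The genes named in the text were also fixed by rule before the data were examined: the 8 largest rises and 8 largest falls with separated arrays in each comparison, up to 4 called members of each list and the member that moved least, the reprogramming factors, and up to 10 genes in each of the position groups. Overlap between the comparisons against fibroblasts was set beside independent lists and beside 100 simulated draws. In these draws all groups were unchanged and both comparisons shared the simulated fibroblast arrays.

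The alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, another percentile or no filter, other fold minimums, limma's treat, trend and robust eBayes, pairs of cell types fitted alone, the replicate number as a term, 1 probe set per gene, the mean of a gene's probe sets, only probe sets without shared sequence, Spearman's rho and leaving out each array. Added after seeing the data were array weights, only steady probe sets, only probe sets in the authors' tables, and scaling to 36 poly-A spike-in probe sets.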

Results

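Gene expression was measured in 3 rhesus monkey cell types on 9 Affymetrix rhesus arrays, with 3 arrays each for adult ear skin fibroblasts, the embryonic stem (ES) cell line R366.4 and the induced pluripotent stem (iPS) cell line M2. iPS cells are made from body cells by adding transcription factors, and ES cells are taken from early embryos. The question named in the series was how similar the reprogrammed cells are to ES cells. Each array gave an intensity for 52865 probe sets, and median intensities ran from 32.1 to 48.9 in arbitrary units. The highest median was on ES replicate 3, where 67.3% of probe sets lay above the filter intensity of 22.45, against 57.1% to 60.2% on the other 8 arrays. The labels call the replicates technical, so p-values measure only the spread between these arrays, not between cultures or animals. Values after ± are SDs over the 3 arrays of a cell type, or SEs where given for a log2 difference. Log2 differences are on the log2(intensity + 16) scale, which understates changes of dim genes.

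Arrays of 1 cell type were on average closer to each other than to other types, but single pairs overlapped. Across the 36978 probe sets tested, the mean Pearson r between arrays was 0.823 within fibroblasts, 0.766 within ES cells and 0.805 within iPS cells. Between types it was 0.709 for ES and iPS cells, 0.591 for fibroblasts and ES cells and 0.555 for fibroblasts and iPS cells. The lowest pair of ES arrays had 0.708 and the highest pair of an ES and an iPS array 0.777. These correlations are across probe sets, which are not independent replicates. Over the 27716 probe sets whose 3 arrays lay within 1 log2 unit of each other in every type, a choice made after seeing the data that raises r within types by construction, the corresponding values were 0.989, 0.982, 0.984, 0.891, 0.736 and 0.686.

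**Figure D1:**
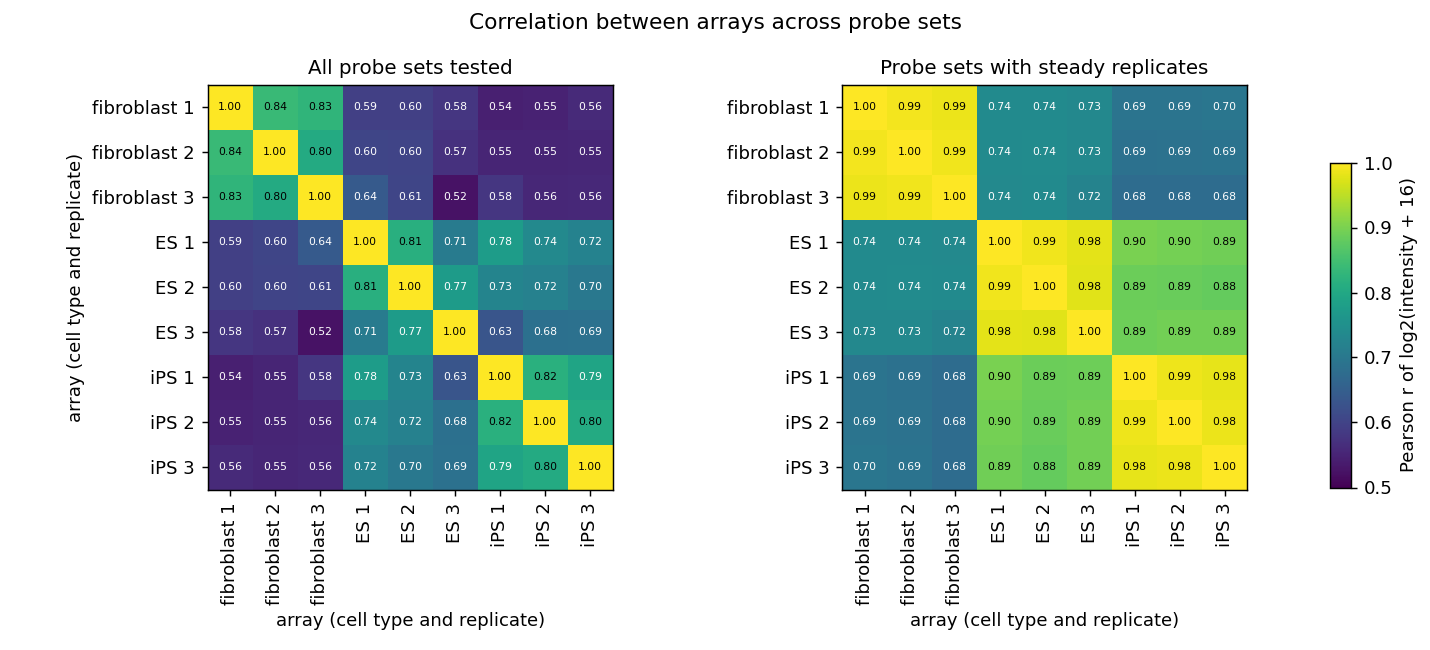
Pearson r of log2(intensity + 16) for every pair of the 9 arrays, over all probe sets tested (left) and over those with steady replicates (right). In both panels the mean r of ES and iPS arrays (0.709 and 0.891) lay above that of fibroblasts with either type, and on the left it lay below that within each type. On the right the choice of probe sets raises r within types, so that comparison shows nothing there.

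In ES cells 12 of 20 pluripotency genes, 18 of 24 mitotic cell cycle genes and 10 of 21 epithelial junction genes were higher than in fibroblasts, and 22 of 31 fibroblast and matrix genes were lower. POU5F1, a central transcription factor of pluripotency, read 30.6 ± 3.18 in fibroblasts and 3346 ± 159 in ES cells, a log2 difference of 6.17 ± 0.08 (SE) with a limma adjusted p of 1.64e-08. SOX2, another factor of that network, rose from 3.45 ± 0.432 to 1358 ± 231, and the DNA methyltransferase DNMT3B from 17.0 ± 2.86 to 1517 ± 126. SPP1, which encodes the secreted protein osteopontin, rose from 7.74 ± 1.02 to 4802 ± 316. The collagen gene COL1A2 fell from 3938 ± 447 to 45.1 ± 5.3, and the small proteoglycan gene LUM from 2099 ± 62.6 to 7.93 ± 1.10.

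By list, 12 of 20 tested pluripotency genes rose and 2 fell, with the same counts of 12 and 2 adjusted over the list alone. DPPA4 was among those that rose, at 17.3 ± 16.5 in fibroblasts and 3236 ± 283 in ES cells. The list as a whole was higher by camera (adjusted p = 0.00148), but not with an estimated correlation (adjusted p = 0.153 with an estimated correlation). Of 31 genes of fibroblasts and extracellular matrix, 22 fell and 3 rose, again 22 and 3 adjusted over the list alone (camera adjusted p = 3.22e-07, and adjusted p = 0.153 with an estimated correlation). DCN, a proteoglycan that binds collagen, fell from 3344 ± 287 to 44.9 ± 4.81, and LOX, which crosslinks collagen, from 2231 ± 230 to 53.5 ± 22.7. Of 23 mesenchymal and contractile genes, 12 fell and 1 rose (12 and 1 adjusted over the list alone), with PRRX1 at 924 ± 101 and 6.55 ± 1.52 and the repressor of epithelial genes ZEB1 at 603.5 ± 52.0 and 53.5 ± 3.85. That list was lower by camera (adjusted p = 9.21e-05, and adjusted p = 0.180 with an estimated correlation).

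Of 21 epithelial junction genes, 10 rose and 1 fell, 10 and 1 adjusted over the list alone. The adhesion molecule EPCAM rose by 5.26 ± 0.08 (SE) on the log2 scale, the tight junction gene CLDN10 went from 6.13 ± 1.02 to 274 ± 9.79 and the junction protein F11R from 184 ± 6.62 to 2020 ± 110. The camera result for this list was an adjusted p of 0.00358, and adjusted p = 0.153 with an estimated correlation. In the mitotic cell cycle list 18 of 24 genes rose and 0 fell, 18 and 0 adjusted over the list alone. They included MCM3 and MCM2, which encode parts of the replicative helicase, at 35.6 ± 2.19 and 45.5 ± 3.24 in fibroblasts and 461 ± 28.2 and 417 ± 59.7 in ES cells. The camera adjusted p was 1.33e-09, and adjusted p = 0.161 with an estimated correlation. Outside the lists, the largest falls of steady genes included EFEMP1, a matrix protein, from 3138 ± 192 to 15.8 ± 3.09, and NUPR1, a stress response gene, from 2434 ± 208 to 10.5 ± 3.54. The factors used most often for reprogramming did not all follow the pluripotency list. MYC fell from 570 ± 27.1 to 223 ± 36.8, KLF4 read 95.9 ± 6.29 and 114 ± 14.9, and the only tested probe set annotated to NANOG fell from 472.5 ± 42.7 to 193.5 ± 5.54. Whether that probe set measures NANOG alone was not tested.

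In all, limma called 7912 of 36978 probe sets (21.4%) between ES cells and fibroblasts, 3330 higher and 4582 lower, at an adjusted p under 0.05 and a change of at least 2-fold. At 1 probe set per gene, 1178 of 12217 genes were higher and 1581 lower. No list passed camera with an estimated correlation in any comparison.

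**Figure D2:**
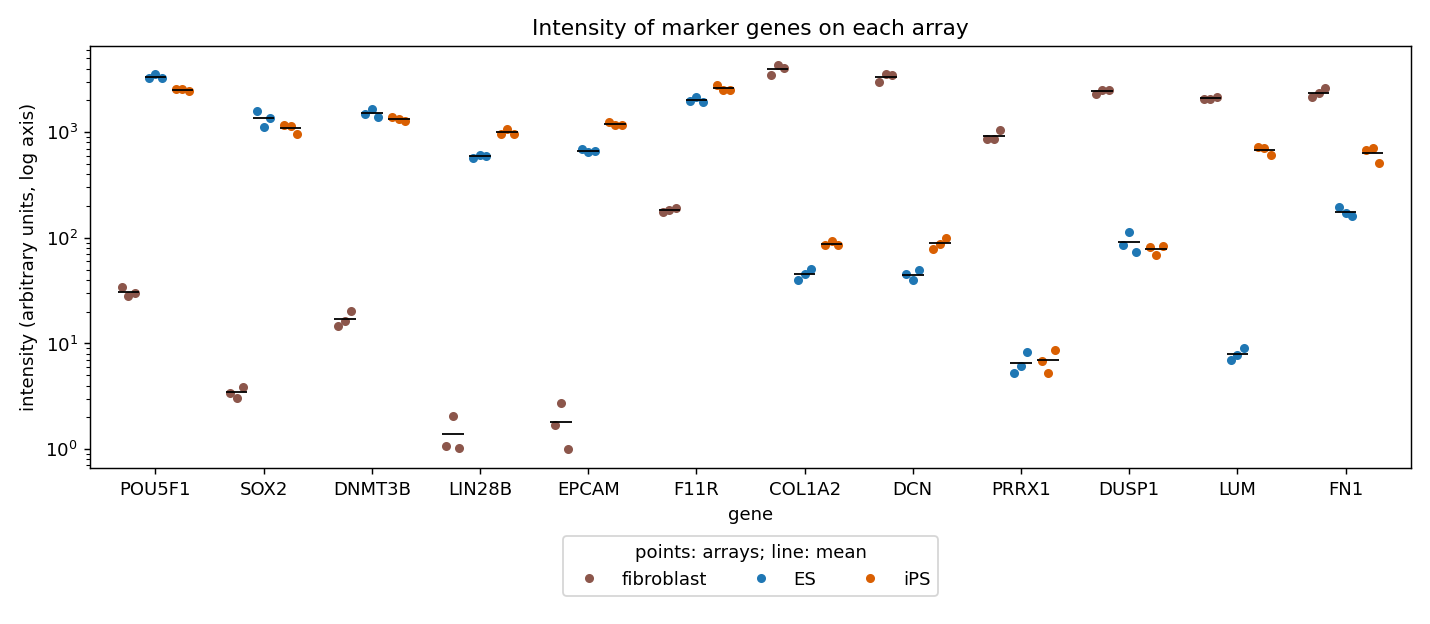
Intensity of 12 genes on each of the 9 arrays, on a log axis in arbitrary units, with points for arrays and a line for the mean of each cell type. POU5F1 read 30.6 in fibroblasts, 3346 in ES cells and 2535 in iPS cells, while LUM read 2099, 7.93 and 677.

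The 5 lists that passed for ES cells against fibroblasts also passed for iPS cells. POU5F1 read 2535 ± 62.5 in iPS cells, a log2 difference from fibroblasts of 5.78 ± 0.08 (SE) with a limma adjusted p of 2.52e-08, SOX2 1087 ± 118 and SPP1 4370 ± 166. LIN28B, which blocks the maturation of let-7 microRNAs, rose from 1.38 ± 0.575 to 994 ± 60.3, and CRABP1, a retinoic acid binding protein, from 5.78 ± 2.89 to 1839 ± 76.3. COL1A2 fell to 87.9 ± 4.23, DCN to 88.4 ± 9.82 and CTSK, a collagen-degrading protease, from 2100 ± 169 to 37.4 ± 4.06. Asporin (ASPN), a matrix protein, fell from 1465 ± 120 to 3.68 ± 0.935.

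Of 20 pluripotency genes, 12 rose and 1 fell, with the same counts of 12 and 1 adjusted over the list alone (camera adjusted p = 0.000865, and adjusted p = 0.153 with an estimated correlation). Of 31 fibroblast and matrix genes, 24 fell and 2 rose, 24 and 2 adjusted over the list alone (camera adjusted p = 3.22e-07, and adjusted p = 0.153 with an estimated correlation). Of 23 mesenchymal and contractile genes, 15 fell and 2 rose, 15 and 2 adjusted over the list alone (camera adjusted p = 0.000436, and adjusted p = 0.202 with an estimated correlation). PRRX1 read 6.93 ± 1.70, ZEB1 28.5 ± 3.56, and CCN1, a matricellular protein, fell from 3140 ± 179 to 436 ± 11.2. Of 21 epithelial junction genes, 12 rose and 0 fell, 12 and 0 adjusted over the list alone (camera adjusted p = 0.000436, and adjusted p = 0.153 with an estimated correlation), with EPCAM at 1197 ± 53.2, F11R at 2597 ± 174 and desmoplakin (DSP) going from 4.71 ± 0.458 to 167 ± 7.89. Of 24 mitotic genes, 19 rose and 0 fell, 19 and 0 adjusted over the list alone (camera adjusted p = 3.67e-08, and adjusted p = 0.180 with an estimated correlation). MCM3 read 322 ± 18.2 and MCM2 267 ± 24.5.

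A further pair of lists passed here that did not pass for ES cells against fibroblasts; the difference between the comparisons is the iPS against ES test given below. Of 23 HOX genes, regulators of body axis identity, 11 rose and 1 fell, 11 and 1 adjusted over the list alone (camera adjusted p = 0.0398, and adjusted p = 0.191 with an estimated correlation). That list result was lost in 5 of 17 alternatives (adjusted p from 0.0139 to 0.191), among them quantile normalization (0.0787) and leaving out replicate 3 of fibroblasts (0.0535), ES cells (0.0513) or iPS cells (0.0605). HOXC6 rose from 3.99 ± 0.206 to 941 ± 30.9, HOXB7 from 5.95 ± 1.35 to 268 ± 30.6 and HOXA5 from 7.93 ± 1.34 to 208 ± 30.8, whereas HOXB1 fell from 2462 ± 523 to 7.56 ± 5.44. Of 12 immediate early and heat shock genes, 6 fell and 0 rose, 6 and 0 adjusted over the list alone (camera adjusted p = 0.0182, and adjusted p = 0.180 with an estimated correlation). The phosphatase DUSP1 fell from 2435 ± 121 to 78.4 ± 8.27 and the AP-1 factor JUNB from 426 ± 139 to 21.0 ± 2.50. Of the reprogramming factors, KLF4 rose from 95.9 ± 6.29 to 454 ± 23.0, MYC fell to 109 ± 4.65 and the probe set annotated to NANOG read 325 ± 16.8.

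Between iPS cells and fibroblasts limma called 10328 probe sets (27.9%), 4459 higher and 5869 lower. Poly-A spike-in controls, bacterial RNAs that are normally added to each sample in fixed amounts before labelling, were 2.24-fold brighter on iPS than on fibroblast arrays and 2.14-fold brighter than on ES arrays. Scaling the arrays to these controls, a choice made after seeing the data, shifts the median log2 difference of all probe sets by -0.87 for iPS against fibroblasts and by -0.80 for iPS against ES cells, so directions for iPS cells are given relative to the median of all probe sets. With that scaling the calls were 1494 higher and 15092 lower for iPS against fibroblasts, and 5 HOX genes rose and 3 fell. It gave 10 higher and 5 lower of the pluripotency genes, 8 and 4 of the epithelial, 4 and 0 of the mitotic, 1 and 26 of the fibroblast and matrix, 0 and 17 of the mesenchymal and 0 and 9 of the immediate early genes.

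Between iPS and ES cells 7 of 20 pluripotency genes were called, as were members of several other lists. POU5F1 read 2535 ± 62.5 in iPS and 3346 ± 159 in ES cells, SOX2 1087 ± 118 and 1358 ± 231, and DNMT3B 1338 ± 57.5 and 1517 ± 126, none of them past the 2-fold minimum, though SOX2 was called, at a log2 difference of -1.12, with the mean of its probe sets. Of the 20 pluripotency genes, 3 were higher and 4 lower in iPS cells, 3 and 4 adjusted over the list alone (camera adjusted p = 0.473), and with scaling to the spike-ins 0 were higher and 10 lower. Higher were the telomerase subunit TERT, at 284 ± 4.81 in iPS and 79.3 ± 8.12 in ES cells, the retinoic acid hydroxylase CYP26A1, at 235 ± 9.31 and 67.1 ± 14.7, and ZFP42, at 231 ± 19.3 and 49.2 ± 1.89. DPPA4 was lower, at 1376 ± 63.1 against 3236 ± 283. Of the reprogramming factors KLF4 was called, at 454 ± 23.0 against 114 ± 14.9 (log2 difference 1.86 ± 0.11, SE; limma adjusted p = 4.14e-05). MYC was not called, but passed with a pseudocount of 1 and without ES replicate 3 (log2 differences of -1.02 and -1.06). For the reprogramming factors, whether the probe sets also read copies added to make the iPS cells was not tested.

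Of 23 HOX genes, 6 were higher in iPS than in ES cells relative to the median of all probe sets, 0 were lower and 17 were not called, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.00822, and adjusted p = 0.153 with an estimated correlation). With scaling to the spike-ins the median of the HOX list went from 0.38 to -0.43. The 5 called HOX genes still tested and the 4 called imprinted genes lost their calls but stayed above 0. Their choice at a log2 difference of at least 1 nearly fixes that sign in advance. HOXC6 read 941 ± 30.9 in iPS and 264 ± 38.4 in ES cells and HOXB7 268 ± 30.6 and 65.0 ± 6.34, while the other tested probe set of HOXC6 differed by 0.44 on the log2 scale. HOXB8 was also called, at 131 ± 18.5 against 34.4 ± 4.14, but its other probe sets had a mean difference of -0.74. Of 16 imprinted genes, expressed from 1 parental copy, 4 were higher and 2 lower, 4 and 2 adjusted over the list alone (camera adjusted p = 0.477). DLK1 read 646 ± 45.5 against 180 ± 32.4, MEST 897 ± 33.1 against 254 ± 38.0 and the noncoding RNA H19 422 ± 30.5 against 125 ± 10.6. GRB10 read 763 ± 74.3 against 303 ± 55.0, a call that its other probe sets (mean difference -0.15) do not share. With scaling to the spike-ins, 0 HOX genes were higher and 1 lower, and 0 imprinted genes were higher and 5 lower.

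Immediate early and heat shock genes were lower in iPS than in ES cells: 4 of 12 fell and 0 rose, 4 and 0 adjusted over the list alone (camera adjusted p = 0.00430, and adjusted p = 0.153 with an estimated correlation). The stress factor DDIT3 read 70.1 ± 14.3 in iPS and 343 ± 20.1 in ES cells, DDIT4 205 ± 12.9 and 476 ± 42.7, and ATF3 114 ± 9.34 and 305 ± 20.3. Of 7 housekeeping genes 1 was lower, B2M, and 1 adjusted over the list alone (camera adjusted p = 0.0448, and adjusted p = 0.310 with an estimated correlation). That list result was lost in 9 of 17 alternatives (adjusted p from 0.0226 to 0.310), among them median centring (0.0536) and 5 settings without 1 array (0.0535 to 0.0678). Fibroblast and matrix genes split, with 5 of 31 higher and 5 lower in iPS cells, 5 and 5 adjusted over the list alone (camera adjusted p = 0.634). LUM was higher, at 677 ± 59.0 against 7.93 ± 1.10 (log2 difference 4.85 ± 0.09, SE; limma adjusted p = 1.46e-07), and its other probe set differed by 3.97. Fibronectin (FN1), measured by a probe set that may cross-hybridise, read 630 ± 107 against 176 ± 18.5. Elastin (ELN) was lower, at 9.98 ± 0.206 against 120 ± 12.8.

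Some of the largest differences were all-or-none in their readings. Such readings also occurred between technical replicates of 1 cell type. SLC4A5 read 1, 1725 and 1724 on the 3 iPS arrays, and RBFOX1 2058, 6.48 and 1942. An all-or-none reading thus does not by itself show that a gene was on or off. LIMK1, a kinase that regulates actin, read 1575 ± 68.1 in ES cells against 2.21 ± 1.18 in iPS cells and 1.84 ± 0.959 in fibroblasts, while its other probe set differed between iPS and ES cells by -0.47. PWWP2B read 2186 ± 98.8, 17.7 ± 0.716 and 6.38 ± 3.29 in the same order. CYP1B1, an enzyme of xenobiotic and steroid metabolism, read 9.36 ± 2.50 in ES, 429 ± 27.0 in iPS cells and 446 ± 29.9 in fibroblasts, and KYNU, an enzyme of tryptophan breakdown, 9.08 ± 2.96, 348 ± 34.6 and 253 ± 21.4. ATP1A4 was bright only in iPS cells, at 343 ± 34.5, and its other probe set differed from ES cells by -0.12.

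Between iPS and ES cells limma called 3632 probe sets (9.82%), 1860 higher and 1772 lower in iPS cells, and at 1 probe set per gene 627 genes were higher and 556 lower. With quantile normalization, which shifts the median of all probe sets by 0.11, the split was 2400 higher and 1343 lower, with a pseudocount of 1 it was 2520 and 2967, with scaling to the spike-ins 284 and 12667, and over only the probe sets in the authors' tables, a choice made after seeing the data, 337 and 806, so which direction has more calls depends on the processing. That scaling also gave 0 higher and 17 lower mitotic genes, 1 and 11 fibroblast and matrix genes, 0 and 9 immediate early genes and 0 and 6 housekeeping genes.

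The similarity of iPS and ES cells was measured over the probe sets that separate ES cells from fibroblasts. Of the 7912 probe sets called for ES cells against fibroblasts, 6317 (79.8%) were not called between iPS and ES cells, 1001 (12.7%) lay on the fibroblast side of ES cells and 594 (7.51%) beyond them. Over all 36978 tested probe sets only 9.82% were called between iPS and ES cells, so the 7912 differed more often than all did. Choosing probe sets on their ES values favours the fibroblast side, so part of that share may come from the choice. The median position of iPS cells was 0.965 (quartiles 0.641 and 1.21), where 0 is the fibroblast level and 1 the ES level. It was 0.790 for the 3330 probe sets higher in ES cells, of which 672 (20.2%) lay on the fibroblast side, and 1.01 for the 4582 lower ones, of which 329 (7.18%) did. This contrast by direction was computed on the main scale only. With spike-in scaling the median position over all called probe sets was 1.11, so the contrast may depend on the processing. The fibroblast side includes values past the fibroblast level. BRF1 and LUM were on that side, and SERPINB6, which was higher in iPS cells than in fibroblasts.

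Both comparisons called 5788 probe sets in the same direction, 1968 higher and 3820 lower, and 24 in opposite directions. Independent lists of these sizes would share 1129. Simulated unchanged groups, set against shared simulated fibroblast arrays, shared 4.87 on average and 11 at most. With no effect in either comparison few probe sets can be called there, so that number is no measure for the 5788. The r of the log2 differences was 0.768 (0.501 with no effect simulated) and their covariance 1.23 (0.201 simulated), which leaves 1.03. The 3 fibroblast arrays are too few to split, so part of the excess may come from the shared controls.

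**Figure D3:**
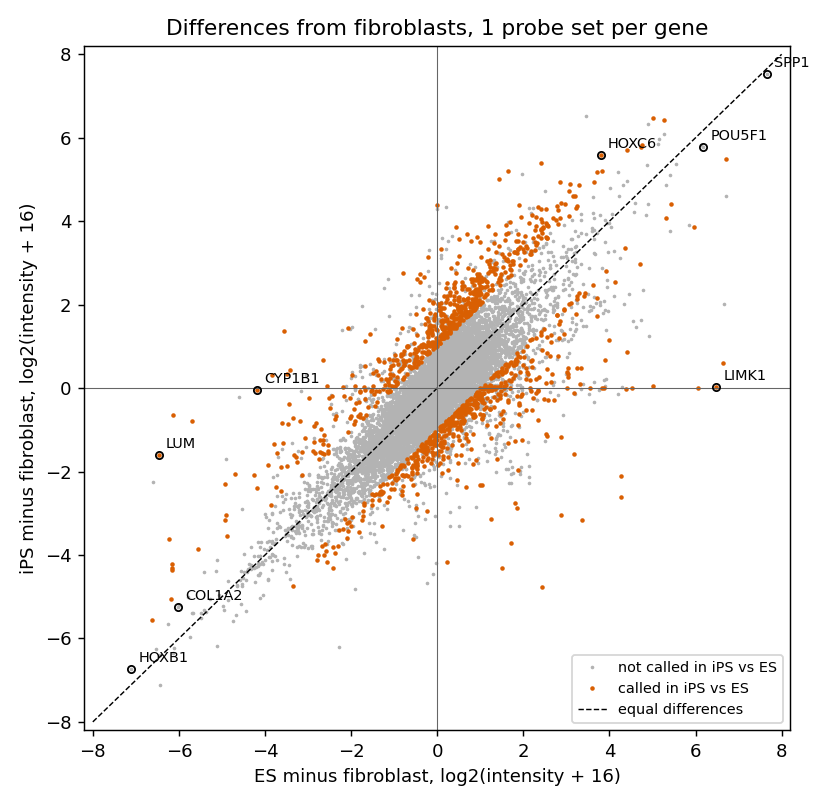
Log2 difference from fibroblasts in ES cells (x axis) and iPS cells (y axis), on the log2(intensity + 16) scale, for 12217 genes at 1 probe set per gene. The 1183 genes called between iPS and ES cells are orange and lie off the dashed line of equal differences, LUM and CYP1B1 on the fibroblast side and HOXC6 beyond ES cells.

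The authors' deposited tables of the 3 comparisons list 14426, 12740 and 12764 probe sets. In the authors' deposited table of iPS against ES cells 87.1% of probe sets were within 2-fold, 810 were at least 2-fold higher in iPS cells and 831 at least 2-fold lower, with r of 0.926 across probe sets. Within 2-fold were 67.7% in the authors' deposited table of ES cells against fibroblasts (r of 0.763) and 62.6% in that of iPS cells against fibroblasts (r of 0.751). Of the probe sets called here that the authors' deposited tables also list, 3696 of 3785, 3899 of 3954 and 950 of 1132 differ at least 2-fold in the same direction there, and 0 in the opposite direction. Those tables hold medians of the same arrays, so the shared direction was nearly fixed in advance and is no independent check. For iPS against ES cells the factor of 1.188 on the iPS medians can also move probe sets across the 2-fold limit.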

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

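The measurements here were looked at only after the data were seen, except the tests on other splits of the arrays, which were planned. A control probe set that should have no target in the samples read 674.5 ± 105 on ES arrays. It read 1.99 ± 0.979 on fibroblast arrays and 1 on every iPS array. Control probe sets were left out of the comparisons, but an all-or-none difference between cell types thus also arose without a known target. Poly-A spike-ins were on average 2.24-fold brighter on iPS than on fibroblast arrays over 36 probe sets (1.86 to 2.73). On ES arrays they were 1.05-fold brighter than on fibroblast arrays (0.568 to 2.79). Against ES arrays they were 2.14-fold brighter on iPS arrays, but single probe sets ranged from 0.747 to 3.31. The hybridisation controls, added after labelling, were 1.79-fold brighter on iPS than on fibroblast arrays over 27 probe sets (1.14 to 9.17). They were 1.26-fold brighter on ES than on fibroblast arrays (0.944 to 7.18) and 1.42-fold brighter on iPS than on ES arrays (1.03 to 1.85). There were 24 probe sets called against fibroblasts in opposite directions in ES and iPS cells, and limma also called all 24 between iPS and ES cells, which their selection nearly fixes in advance. Of these 15 were higher in ES and lower in iPS cells and 9 the other way, among them SERPINB6, which read 609.6 in fibroblasts, 39.2 in ES and 1601 in iPS cells, and TCTN2, which read 154, 565 and 8.78.

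Splits of 6 arrays are too few for a share under 0.05: 1 of 10 splits called as many probe sets as the real one in each pair of cell types, with 7776 against 219 at most in the other splits for ES cells and fibroblasts, 10444 against 111 for iPS cells and fibroblasts, and 3387 against 177 for iPS and ES cells. Over all 9 arrays, 1 of 100 drawn splits gave as many differing probe sets as the real one, 22726 against 11489 at most, which excludes chance only as a grouping of these arrays. The arrays of a type are technical replicates, so these splits say nothing of cultures or animals. For the list tests 3 of 100 splits, the real one included, gave as many passing lists as the real 15, with 15 the highest of the others, a share under 0.05 by a small margin. Many other splits also gave passing lists, such as 15 lists at 35 differing probe sets, while others gave 0. Lists can thus pass at the preset correlation without the real grouping.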

How the results depend on the processing

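The tests with array weights, steady probe sets, the authors' tables and spike-in scaling were chosen after the data were seen. Of 157 main values under the alternatives 46 moved. These are counts, positions, overlaps and correlations, for which no reversal was defined, so turns in the split of higher and lower calls are not covered. Named genes and list tests were not rerun with array weights, the authors' tables or spike-in scaling. Their totals, and the numbers of alternatives given for single lists, leave these settings out. The HOX median between iPS and ES cells, 0.38 in the report and -0.43 with spike-in scaling, is therefore not covered by them. Of 4260 values for named genes 253 lost the call, 3 gained it and 3 reversed, and of 1428 list tests 27 lost and 21 gained significance. The cause was not tested unless a setting itself sets it, as a fold minimum, treat or 1 probe set per gene does for the main values.

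Position (0.965 in the report) was 0.936 with quantile normalization, 0.956 with median centring, 0.976 with a pseudocount of 1, 0.971 with 64, 0.980 with the 60th percentile, 0.990 without a fold minimum, 0.955 with log2 differences of at least 2, 0.969 with treat, 0.950 with 1 probe set per gene, 0.977 with steady probe sets, 0.959 with array weights and 1.11 with spike-in scaling. Leaving out 1 array gave 0.9295 to 0.974.

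Calls for ES against fibroblasts, iPS against fibroblasts and iPS against ES cells were 4607, 5920 and 1455 with a pseudocount of 64 (overlap 3383), 16619, 20293 and 12863 without a fold minimum (overlap 12952), 2673, 3493 and 577 with log2 differences of at least 2 (overlap 1884), 4038, 5488 and 618 with treat (overlap 3026), 2775, 3468 and 1194 with 1 probe set per gene (overlap 2031), and 3800, 3981 and 1143 in the authors' tables (of these 1372, 1110 and 337 higher and 2428, 2871 and 806 lower). A pseudocount of 1 gave 5487 calls for iPS against ES cells, and spike-in scaling 16586 and 12951 for iPS against fibroblasts and ES cells. Leaving out 1 array gave 7786 to 8205, 10131 to 10529 and 3324 to 3916 calls, and without ES replicate 3 they were 7995, 10529 and 3820.

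The mean r of ES and iPS arrays was 0.642 with a pseudocount of 1, 0.752 with 64, 0.647 with the 60th percentile and 0.891 with steady probe sets. With an estimated correlation 0 lists passed, against 15. The HOX result in iPS cells against fibroblasts was lost with quantile normalization (adjusted p = 0.0787) and without replicate 3 of fibroblasts, ES or iPS cells (0.0535, 0.0513 and 0.0605), and the housekeeping result with median centring (0.0536), the mean of probe sets (0.0538), steady probe sets (0.0789) and in 5 settings without 1 array (0.0535 to 0.0678). The mean of all probe sets turned MAMU-A in ES cells to 0.15, HOXB8 between iPS and ES cells to -0.17 and TFRC in iPS cells to 0.13, while lists that did not pass in the report passed in some alternatives. Lysosome genes in iPS cells against fibroblasts passed in 9 of 17, with quantile normalization (adjusted p = 0.0448), median centring (0.0470), a pseudocount of 1 (0.0257), the mean of probe sets (0.00405), steady probe sets (0.0260) and in 4 settings without 1 array (lowest 0.01497), and the highest value over all 17 was 0.422 with an estimated correlation. Between iPS and ES cells inflammatory genes passed in 2 of 17 (0.0108 with the mean of probe sets, 0.0137 with steady ones, range to 0.204), trophoblast genes in 2 (0.0352 with the mean of probe sets, 0.0372 without ES replicate 2) and melanocyte genes in 1. In ES cells against fibroblasts p53 genes passed in 4 and DNA methylation genes in 2, and in iPS cells p53 genes in 1.

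With a replicate block the calls were 7826, 10281 and 3498, position 0.965, overlap 5742 and 15 lists passing, and no count moved by over 1.5 times. Same-numbered arrays did not deviate together across all types, with 2 of 9 correlations over 0.1 (range -0.22 to 0.21). Both were between ES and iPS arrays, 0.21 for replicate 1 and 0.16 for replicate 3. Differently numbered arrays were not set beside them, so whether the numbers pair samples stays open.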

Other observations

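The tests with spike-in scaling and the tests of explanations in the closing paragraphs were all chosen after the result was seen, and the gene lists described first were fixed before the data were examined. DNA methylation and chromatin genes split: 6 of 22 rose and 2 fell in ES cells, 7 and 4 in iPS cells, and 0 and 2 between iPS and ES cells. JARID2, a Polycomb cofactor, read 111 ± 3.29 in fibroblasts, 1190 ± 106 in ES and 939 ± 16.9 in iPS cells, and UHRF1, which maintains DNA methylation, 342 ± 37.9 in ES and 132 ± 11.6 in iPS cells. Of the genes of p53 and growth arrest 0 of 17 were higher and 5 lower in ES cells, 1 and 8 in iPS cells and 1 and 3 between iPS and ES cells. GADD45A read 1496 ± 5.43, 342 ± 12.2 and 473 ± 11.3 in fibroblasts, ES and iPS cells. Lysosome and autophagy genes were 0 higher and 6 lower of 16 in ES cells, 0 and 8 in iPS cells and 0 and 3 between them, with SQSTM1 at 1501 ± 130 in fibroblasts and 288 ± 39.2 in ES cells. In glycolysis 4 of 19 rose and 4 fell in each pluripotent line, with 0 higher and 1 lower between iPS and ES cells; SLC2A1, a glucose transporter, read 136 ± 8.47 in fibroblasts and 741 ± 87.0 in ES cells, and ENO2 fell from 2284 ± 213 to 387 ± 46.0. Mitochondrial respiration had 0 higher and 2 lower of 18 in each pluripotent line and 0 and 0 between them, COX7A1 among the lower. For FGF, Nodal and WNT signalling 3 of 29 rose and 5 fell in ES cells, 7 and 4 in iPS cells and 1 and 1 between them, with DKK3 at 2647 ± 269, 82.9 ± 2.84 and 39.95 ± 4.13.

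Imprinted genes had 7 of 16 higher and 3 lower in ES cells and 6 and 3 in iPS cells against fibroblasts, HOX genes 7 and 1 of 23 in ES cells. Inflammatory cytokine genes had 2 of 16 higher and 5 lower in ES cells, 6 and 5 in iPS cells and 5 and 0 between iPS and ES cells, and CCL2 read 785 ± 33.5, 11.1 ± 2.08 and 52.6 ± 4.94. Of 23 interferon and antigen presentation genes 2 rose and 5 fell in ES cells, 4 and 5 in iPS cells and 1 and 1 between them. Endoderm genes had 1 of 13 higher and 1 lower in ES cells, 5 and 0 in iPS cells and 3 and 0 between them. Trophoblast genes had 1 and 1 of 10 in ES cells, 2 and 1 in iPS cells and 3 and 0 between them, mesoderm genes 1 and 2 of 14, 1 and 2, and 0 and 1, germline genes 0 and 0 of 6, 1 and 0, and 0 and 0, ectoderm genes 1 and 0 of 7, 1 and 0, and 0 and 0, and muscle genes 1 and 0 of 8, 1 and 2, and 0 and 1. For markers of other skin or blood cells the pairs were 2 and 0 of 7 for keratinocytes, 2 and 0, and 1 and 1; 1 and 0 of 7 for melanocytes, 2 and 0, and 2 and 0; 4 and 0 of 11 for endothelium, 3 and 0, and 1 and 3; and 1 and 1 of 8 for blood cells, 3 and 0, and 1 and 0. Housekeeping genes had 0 and 1 of 7 in ES cells and 0 and 3 in iPS cells against fibroblasts, reprogramming factors 2 and 2 of 5, 3 and 1, and 1 and 0, and the immediate early list 1 and 3 of 12 in ES cells. Between iPS and ES cells mesenchymal genes had 2 higher and 3 lower, epithelial genes 1 and 1 and mitotic genes 0 and 1. None of these lists passed camera in limma in these comparisons, the lowest adjusted p being 0.0542 for lysosome genes in iPS cells against fibroblasts, a list that passed in 9 of 17 alternatives. The counts adjusted over the list alone were the same except 3 and 1 for trophoblast in iPS cells, 1 and 0 for blood cells in ES cells and 1 and 2 for epithelial genes between iPS and ES cells. Median, mean and camera direction of a list differed in sign against fibroblasts for germline, inflammatory and FGF, Nodal and WNT genes in both pluripotent lines and for mesoderm, glycolysis, blood and muscle genes in ES cells, and between iPS and ES cells for reprogramming, p53, respiration, endothelial and muscle genes.

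Scaling to the poly-A spike-ins divides all intensities of an array by 1 factor. This lowers iPS values against the other types, so more lower calls follow from the shift itself. Of the list members called higher in iPS cells and still tested, 110 of 112 against fibroblasts and 38 of 40 against ES cells stayed above 0, and 0 turned to a lower call. These members had log2 differences of at least 1, and the spike-ins were 2.24-fold and 2.14-fold brighter on iPS arrays. Their selection thus nearly fixed this outcome in advance. Against fibroblasts and against ES cells, higher and lower counts were then 4 and 6, and 0 and 13 for DNA methylation genes, 1 and 9, and 0 and 7 for p53, 0 and 10, and 0 and 9 for lysosome, 1 and 12, and 0 and 13 for glycolysis, 0 and 15, and 0 and 9 for respiration, and 1 and 11, and 0 and 12 for FGF, Nodal and WNT genes. They were 0 and 11, and 0 and 8 for interferon, 3 and 6, and 1 and 3 for inflammatory, 2 and 4, and 0 and 5 for endoderm, 2 and 2, and 1 and 2 for trophoblast, 0 and 3, and 0 and 2 for mesoderm, 0 and 1, and 0 and 2 for germline, 1 and 1, and 0 and 2 for ectoderm, and 1 and 4, and 0 and 5 for muscle genes. For keratinocytes they were 1 and 1, and 0 and 1, for melanocytes 2 and 1, and 0 and 1, for endothelium 0 and 1, and 0 and 3, for blood cells 1 and 1, and 0 and 1, and for reprogramming factors 2 and 2, and 0 and 3. Against fibroblasts alone they were 4 and 4 for imprinted and 0 and 7 for housekeeping genes, and against ES cells alone 0 and 10 for mesenchymal and 0 and 8 for epithelial genes.

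Several exploratory looks at the data came before the patterns weighed here, including intensity bins and probe sets for viral and reporter sequences, and only these 3 patterns are weighed. Of 313 tested probe sets for viral and reporter sequences, 28 were higher and 12 lower in iPS than in ES cells. Over all 36978 tested it was 1860 and 1772. Against fibroblasts 51 of the 313 were higher and 14 lower in iPS cells, and 31 and 17 in ES cells. What these probe sets measured was not tested. On some arrays a probe set read far above both sister arrays, 4620 times in all and 1390 times on ES replicate 3. Of these values 84.81% were above 100 intensity units (88.8% on ES replicate 3), which argues against noise at the floor of the scale for most of them, but only 45.5% of the 123 on ES replicate 1 were, where such noise stays open, and the test says nothing of sister values that fell to the floor. If another RNA had been on ES replicate 3, other probe sets of the same genes would jump there too, and 2.504% of 639 did, against 2.95% of all named probe sets. Both used a definition on plain intensities, which replaced one on log2(intensity + 16) that allowed no jump under 100 and gave 1.69% of 474 other probe sets, against 2.11%; no biological explanation was tested.

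Probe sets dark in fibroblasts were more often higher than lower in iPS against ES cells, 786 against 379 of 5782, while the others went 1074 against 1393 of 31196. A higher gain of the iPS arrays could produce this. The first test of that compared probe sets bright in ES cells that were dark in fibroblasts with those that were not, and the difference of medians was -0.4035 (95% interval -0.66 to -0.28), opposite to the pattern and undecided, since choosing on ES brightness lowers iPS against ES. A second test, chosen after that result, gave a median of -0.11 for 11052 steady probe sets over 100 in ES cells and not dark in fibroblasts, which were chosen on ES brightness as well and whose value the between-array scaling may also fix in advance, so a higher gain cannot be told apart from the pattern. Other probe sets of the same genes differed by a median of 0.1158 (95% interval 0.00254 to 0.193) against 1.40 for their own. The low median is what signal of single probe sets without their transcript predicts, but selection of calls partly fixes the 1.40. Probe sets not dark in fibroblasts gave 0.117 as well. Of the other probe sets 6.74% were called higher for the dark ones and 18% for those not dark. For probe sets lower in iPS than in ES cells the others had a median of -0.461 (95% interval -0.576 to -0.349). The 95% intervals here and in the next paragraph resample probe sets or genes, not arrays. They do not measure the spread between arrays, cultures or animals. Differences between the lines or cultures stayed untested.

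Some probe sets lay on the fibroblast side in iPS cells. Fibroblast RNA in the iPS samples is one candidate explanation, and it would bring all abundant fibroblast transcripts alike. The fibroblast share was taken as the iPS minus ES level in percent of the fibroblast minus ES level. Over 112 probe sets bright in fibroblasts and dark in ES cells its median was 1.03%, with quartiles of 0.014% and 4.37%. LUM was at 32.0%, CYP1B1 at 96.2% and COL1A2 at 1.10%. Of the 112, 10 were at or above the LUM value, LUM among them. The low median argues against fibroblast RNA at the level that LUM would need. Other probe sets of the genes higher in iPS than ES cells had a median difference of 0.2651 (95% interval 0.11 to 0.44), so signal of single probe sets without their transcript stayed undecided. Donor sequence differences, feeder cell RNA and the culture of each line were not tested.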
